A study of Mus musculus with 12 samples.

How the data were processed

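Bone marrow cells of wild-type male C57BL/6 mice had been cultured with 10 ng/mL M-CSF, the growth factor that drives macrophage differentiation. The macrophages then received 20 ng/mL IL4 for 24 h, or the same medium without it, and after washing 1 µM all-trans retinoic acid (RA) or its vehicle DMSO for 6 h. Stranded poly(A) libraries (TruSeq) were sequenced for 101 cycles from 1 end on 1 NovaSeq lane. The 12 libraries fell into 4 groups of 3, called here naive vehicle, naive RA, IL4 vehicle and IL4 RA, each with the replicate numbers 2, 3 and 4 in its titles. Nothing in the labels says whether the replicates came from separate animals or separate cultures, so the p-values measure only the spread between these samples.

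Per the labels, the submitters used bcl2fastq 2.20, Salmon 0.13.1 and edgeR 3.32.1 with genome build GRCm38. The deposited values were log2 CPM (counts relative to library size), scaled by the authors with TMM factors and with a small prior count added. The table held 13553 genes by Entrez ID, 38 of them without a symbol. All 12 libraries shared 1 lowest value, -3.67 (0.0783 CPM), which stands for a count of 0, and every gene exceeded -1.24 in at least 3 libraries. Back on the linear scale the libraries summed to between 950904 and 1056490 CPM. Gene positions were taken from RefSeq (GRCm38.p6), in which 13404 of the 13553 Entrez IDs were found, and strands from GENCODE vM21.

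Read counts were not analysed here. The depth was estimated from the smallest steps between values just above the lowest value, which gave effective library sizes of 30.9 to 48.1 M reads and rest on 4 to 17 genes per library. A single read was then worth 0.0208 to 0.0324 CPM. The IL4 RA libraries were the shallowest by this estimate, at 30.9, 32.2 and 31.8 M reads. For 7370 genes above 16 CPM, the median squared difference between 2 replicates of a group was 2.83 to 8.15 times that of Poisson counting at this depth. Genes below that level were not part of this calculation.

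Genes with at least 1 CPM in at least 3 libraries were tested (12116 of 13553; 1437 removed). The deposited log2 values were used as they are, with 1 linear model in limma 3.58.1 (R 4.3.3), 1 mean per group over all 12 libraries, and moderated statistics with an intensity trend. The 5 contrasts were the RA effect in naive cells, the RA effect in IL4 cells, the IL4 effect in vehicle, the IL4 effect in RA, and the interaction, which is the RA effect in IL4 cells minus that in naive cells. P-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, and genes with adjusted p under 0.05 were called. Changes are log2 differences of group means with the model's standard error (SE) and n = 3 per group; group levels are log2 CPM with their SD.

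Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists with at least 5 tested members. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, were run beside it. The lists, the model, the filter, the alternatives and the rule for named genes were fixed before the data were examined. That rule took, per contrast, the 8 largest increases and the 8 largest decreases among called genes that had at least 4 CPM in the higher group and, the interaction apart, no overlap between groups. Predicted genes were left out, up to 3 called members of each list of the study question were added, and Cyp26a1, Cyp26b1, Rarb, Dhrs3, Arg1, Retnla, Chil3, Mrc1, Abca1, Abcg1 and Tgm2 were always included where measured. Cyp26a1 was not analysed here. Other genes named are members of a list, or are stated to have been named after their values were seen.

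Because the groups share replicate numbers, the correlations between same-numbered libraries of their deviations from the group means were computed. They were 0.245, 0.193 and 0.128 between the IL4 groups and 0.140, 0.209 and 0.182 between the vehicle groups, each above 0.1. Between the naive groups they were 0.510, 0.277 and 0.0706 and between the RA groups 0.0895, 0.186 and 0.126, so 1 value of each lay below 0.1, although 12 of 12 libraries were on average closest to their own number in the other groups. For the contrasts within IL4 cells and within vehicle the numbers were taken to pair the libraries, from the data and not from the labels, and a fit with the replicate block was made as an alternative.

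The model was tested on simulated data in which 200 of the 12116 genes were changed. For the RA effect in naive cells it recovered 79.1% of changes of 0.5 (log2) and 97.0% of changes of 1. For the interaction it recovered 59.7% and 89.6%. The simulated genes were independent, with normal noise and no differences between replicate numbers, so recovery in the real data may differ. Alternatives were no filter, a filter at 4 CPM, centring each library on its median, quantile normalization, no intensity trend, robust moderation, library weights, a fold threshold, the replicate block, fits of only the compared groups, and leaving out each library in turn.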

Results

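Polyadenylated RNA of 12 libraries of mouse bone marrow derived macrophages was compared across 4 groups of 3: naive or IL4-stimulated cells, each given RA or vehicle for 6 h. RA is the vitamin A metabolite that activates nuclear retinoic acid receptors, and IL4 is the cytokine used to induce the alternative activation state of macrophages. Lyz2, which encodes lysozyme, held the largest share of the signal in all 6 naive libraries, and Fth1, the ferritin heavy chain, in all 6 IL4 libraries. The 10 most abundant genes took 11.3% to 13.5% of each library. Replicates of a group correlated at Pearson r of 0.992 to 0.995 across genes, which are not independent replicates. The leading principal component, on which IL4 separated from naive libraries, held 79.8% of the variance, and the next held 6.38%.

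What RA does to naive macrophages was asked first. Rarb, a retinoic acid receptor gene and a known direct target of RA (Entrez 218772, chromosome 14, 16430839 to 17082331, minus strand), rose from -2.69 ± 0.40 to 1.42 ± 0.24 log2 CPM (SD, n = 3), a change of 4.11 (SE 0.23, adjusted p = 1.3e-07). The kinase gene Camkk1 rose by 4.10, the bone morphogenetic protein gene Bmp2 by 3.17, the transcriptional repressor gene Hic1 by 3.14, the RA-degrading enzyme gene Cyp26b1 by 3.09, Pram1 by 2.47 and the chemokine gene Cxcl14 by 2.27. Il1a, an interleukin 1 gene, rose by 1.60. Plxna4os1, an antisense transcript inside the semaphorin receptor gene Plxna4, rose by 2.11, Ptgs1, which encodes cyclooxygenase 1, by 1.79 and Hivep2 by 1.73. Arg1, the arginase that marks alternative activation (Entrez 11846, chromosome 10, 24915207 to 24927470, minus strand), rose by 1.92 (SE 0.17, adjusted p = 9.7e-06), but from -2.32 ± 0.30 to only -0.40 ± 0.22 log2 CPM. In naive vehicle Rarb, Hic1, Cyp26b1 and Arg1 all lay at or below -1.98 log2 CPM, not far above the lowest value, so their folds are inexact. Decreases were smaller: the nuclear envelope gene Syne3 fell by 0.89, the lymphatic growth factor gene Vegfc by 0.79, the cyclooxygenase 2 gene Ptgs2 by 0.71, and the checkpoint ligand gene Cd276 by 0.69. Slc9b2, the adenosine receptor gene Adora2b and the phosphatase gene Dusp1 fell by 0.68 each, and Tiam1 by 0.66. Retnla, Chil3 and Mrc1, which IL4 induces, differed by -0.02, -0.19 and -0.17 and were not called (adjusted p = 0.98, 0.79 and 0.19), nor were the cholesterol transporter genes Abca1 (0.18, adjusted p = 0.14) and Abcg1 (-0.02, adjusted p = 0.91). Abca1 was called without IL4 RA library 2 (0.0308) and with library weights (0.00742).

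Among the retinoic acid-inducible genes, 6 of the 10 tested members rose in naive cells and 0 fell: Rarb, Hic1, Cyp26b1, the ectoenzyme gene Cd38 (1.05), the transglutaminase gene Tgm2 (0.74) and the retinaldehyde reductase gene Dhrs3 (0.63). Camera called the list (adjusted p = 2.0e-06), with adjusted p = 0.073 with an estimated correlation. The counts adjusted over the list alone were 6 up and 1 down. Of the TGF-beta and tissue remodelling genes, 3 of 26 rose (the signal transducer Smad3 by 1.20, the collagen gene Col4a2 by 0.88, the protease gene Mmp9 by 0.71) and 4 fell, among them Tgfbi by 0.41 (4 and 4 adjusted over the list alone). That list was not called (adjusted p = 0.90; median -0.04, mean 0.08). Of the classical inflammatory genes, 6 of 31 rose, including Il1a and the chemokine gene Cxcl3 (1.40), and Ptgs2 fell, with 7 and 1 adjusted over the list alone. The list missed the threshold (adjusted p = 0.091), and passed it without naive vehicle library 3 (0.0376), naive vehicle library 4 (0.0378), naive RA library 2 (0.00558) or IL4 vehicle library 2 (0.0415). It also passed with the replicate block. For the interferon-stimulated genes, 0 of 37 were called (adjusted p = 0.46; 0 adjusted over the list alone), while 28 had a positive difference. Leaving out naive RA library 2 (2.7e-08) or naive vehicle library 3 (0.00653) turned the list into a call. Cholesterol biosynthesis genes were lower as a list (adjusted p = 0.0204; median -0.11; 20 of 24 negative), with adjusted p = 0.91 with an estimated correlation. Only Insig1, a brake on sterol synthesis (0.28), rose, and Msmo1, a sterol synthesis enzyme gene, fell by 0.21. Adjusted over the list alone it was 1 and 2. That list call was lost without naive vehicle library 2 (0.234) or 4 (0.102), or naive RA library 3 (0.122) or 4 (0.146). Insig1 lost its call without naive vehicle library 3 (0.0693) or 4 (0.0634) or naive RA library 2 (0.0866) or 3 (0.0711), and Msmo1 without naive vehicle library 2 (0.101) or 4 (0.142) or naive RA library 3 (0.0971) or 4 (0.0956). Gatm, a creatine synthesis gene, rose by 0.95.

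In this contrast 759 of 12116 genes were called, 392 higher and 367 lower with RA. Of these, 754 had no overlap between the groups of 3, which the selection of called genes from the same libraries largely brings about. The median size of a called change was 0.31 (log2), and 50 genes reached 1, 49 of them higher and 1 lower. The count was 505 without naive vehicle library 2, 416 without naive vehicle library 4, 500 without naive RA library 3 and 452 without naive RA library 4. Without naive vehicle library 4, Ptgs2 (adjusted p = 0.0566) and Vegfc (0.0505) were no longer called.

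The same question was asked of IL4-stimulated macrophages. Hic1 (chromosome 11, 75161377 to 75170255, minus strand) rose from -0.21 ± 0.21 to 4.19 ± 0.13 log2 CPM, a change of 4.40 (SE 0.22, adjusted p = 2.2e-08). Camkk1 rose by 3.47, Rarb by 3.45, Pram1 by 2.82, Cyp26b1 by 2.77, and Bmp2 by 2.76. The fold of Cyp26b1 is inexact, since it lay at or below -2.2 log2 CPM in IL4 vehicle. Also higher were the Notch-modifying glycosyltransferase gene Mfng (2.53), the myeloid transcription factor gene Cebpe (2.22) and Smad3 (2.09). Arg1, already abundant after IL4, rose from 6.19 ± 0.26 to 7.93 ± 0.18 log2 CPM, by 1.74 (SE 0.17, adjusted p = 1.4e-05). The interferon-gamma-inducible chemokine gene Cxcl9 (Entrez 17329, chromosome 5, 92321331 to 92328079) fell by 1.65 (SE 0.30, adjusted p = 0.0031), the guanylate-binding protein gene Gbp4 by 1.53, and the chloride channel gene Clic5 by 1.52. The nitric oxide synthase gene Nos2 fell by 1.24, the GTPase gene Iigp1 by 1.14, Ptgs2 by 1.08, Hr by 1.00 and Cracdl by 0.90. IL4 vehicle library 4 lay below libraries 2 and 3 for Cxcl9 (3.22 against 4.59 and 4.39) and Gbp4 (4.13 against 5.58 and 5.67). The same held for Clic5 (2.71 against 3.89 and 4.13) and Iigp1 (4.87 against 5.92 and 5.79). For these genes library 4 still exceeded every IL4 RA library, but the size of the decrease depends on the library. Abca1 rose by 0.52 and Abcg1 fell by 0.29. Retnla (0.22, adjusted p = 0.71), Chil3 (0.03, adjusted p = 0.97) and Mrc1 (-0.09, adjusted p = 0.47) were not called.

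Retinoic acid-inducible genes again had 6 of 10 members higher and 0 lower, with Tgm2 at 1.15, Cd38 at 0.93 and Dhrs3 at 0.80 (adjusted p = 2.9e-07, adjusted p = 0.051 with an estimated correlation; 6 and 0 adjusted over the list alone). Classical inflammatory genes split: Il1a (1.80), Cxcl3 (1.51), the scavenger receptor gene Marco (1.11) and 4 others rose, while Cxcl9, Nos2, Ptgs2, Tnf (-0.59) and 3 others fell, out of 31 (9 and 7 adjusted over the list alone). That list was not called (adjusted p = 0.98; median -0.10, mean 0.02). Of the alternative activation genes 4 of 30 rose, namely Arg1, Ptgs1 (1.28), Batf3 (0.62) and Cd83 (0.29), and 2 fell, Socs1 by 0.81 and Egr2 by 0.24 (list adjusted p = 0.17; 4 and 3 adjusted over the list alone). The interferon-stimulated genes were lower as a list (adjusted p = 6.1e-07; median -0.37; 36 of 37 members negative), with adjusted p = 0.80 with an estimated correlation. A single member, the RNA sensor gene Ifih1, was called (-0.49, adjusted p = 0.037), and 0 adjusted over the list alone. Glycolysis and hypoxia genes were higher (adjusted p = 2.9e-04, adjusted p = 0.69 with an estimated correlation): 6 of 22 rose, among them Vegfa (1.14), Pfkl (0.78), Hk2 (0.44) and Hif1a (0.43), and Pfkp (-0.34) and Pfkfb3 (-0.25) fell, with 13 and 3 adjusted over the list alone.

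Macrophage identity genes were higher with RA in IL4 cells (adjusted p = 0.0144, adjusted p = 0.15 with an estimated correlation), with 5 of 17 called up, such as the Fc receptor gene Fcgr3 (0.36) and the chemokine receptor gene Cx3cr1 (0.32). That makes 7 up and 1 down adjusted over the list alone. The peritoneal macrophage programme passed narrowly (adjusted p = 0.0441, adjusted p = 0.18 with an estimated correlation), with 2 of 12 called, Naip1 (1.23) and the apolipoprotein gene Apoc2 (0.90), and 5 adjusted over the list alone. Efferocytosis genes, which act in the uptake of dead cells, missed the threshold (adjusted p = 0.0627), with the receptor genes Timd4 (1.30) and Stab1 (0.64) among 5 of 22 that rose and Anxa1 (-0.29) falling, also adjusted over the list alone. The identity call was lost without IL4 vehicle library 3 (0.0522) or IL4 RA library 4 (0.0536), and the peritoneal call without IL4 vehicle library 3 (0.0503) or 4 (0.102) or IL4 RA library 3 (0.0643) or 4 (0.0709). Efferocytosis passed without naive vehicle library 2 (0.0499) or 3 (0.0433), IL4 vehicle library 4 (0.0381) or IL4 RA library 3 (0.0398).

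RA changed 1416 of 12116 genes in IL4 cells, 788 higher and 628 lower. Of these, 1399 had no overlap between groups, again largely through the selection of called genes. The median called change was 0.30 and 95 genes reached 1, 81 higher and 14 lower. Without IL4 RA library 3 the count was 894. The call of Iigp1 was lost without IL4 vehicle library 2 (0.0737) or 3 (0.0721) or IL4 RA library 4 (0.0591). That of Cracdl was lost without IL4 vehicle library 2 (0.0565) or IL4 RA library 2 (0.0549) or 3 (0.0515), that of Ifih1 without naive vehicle library 4 (0.0545), IL4 vehicle library 2 (0.135) or 3 (0.0925) or IL4 RA library 3 (0.129) or 4 (0.108). Abcg1 lost its call without IL4 vehicle library 3 (0.108) or 4 (0.102) or IL4 RA library 2 (0.0915), 3 (0.0567) or 4 (0.0618).

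**Figure D1:**
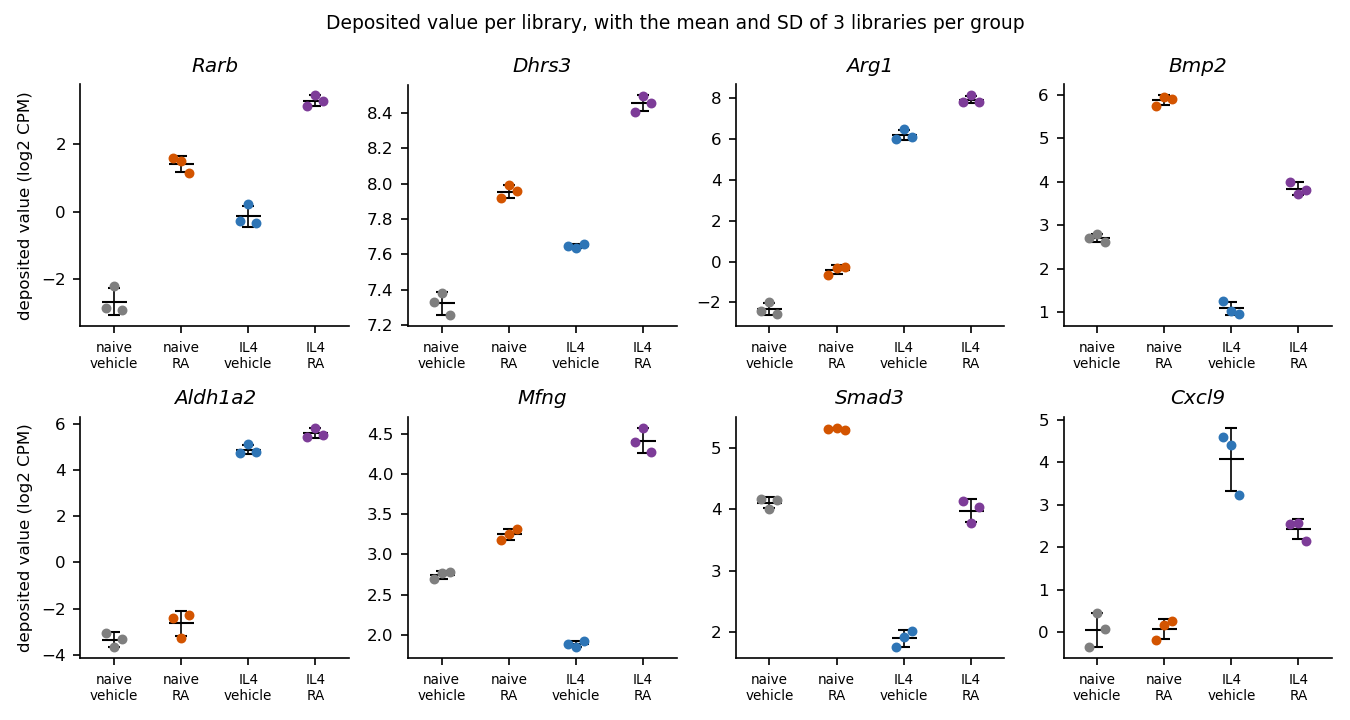
Deposited values (log2 CPM) of 8 genes in each of the 12 libraries, with points for libraries, a bar for the mean of 3 and whiskers for the SD. Arg1 rose by 1.92 with RA in naive cells and by 1.74 in IL4 cells, from starting levels of -2.32 and 6.19.

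What IL4 does in cells then given vehicle gives the reference state for both. Retnla, an IL4-induced secreted protein gene (Entrez 57262, chromosome 16, 48842609 to 48844461, plus strand), rose from -3.17 ± 0.60 to 7.53 ± 0.24 log2 CPM, by 10.70 (SE 0.29, adjusted p = 5.5e-12), with naive values close to the lowest in the table. Chil3, a chitinase-like protein gene, rose by 9.11, Arg1 by 8.51, the RA-synthesizing enzyme gene Aldh1a2 by 8.23, the chemokine gene Ccl17 by 8.14, the lectin gene Mgl2 by 7.51 and the fusion gene Ocstamp by 6.93. Naive vehicle values of Aldh1a2 (-3.045, -3.67 and -3.30) and Ccl17 (-3.065, -3.27 and -3.67) also lay at or near the lowest, so these folds are inexact. That of Arg1 is also inexact, from naive vehicle values at or below -1.98. Rnase2a stood at the lowest value of the table in all 6 naive libraries and at 4.39 ± 0.29 in IL4 vehicle, and no fold is given for it. The transcription factor gene Egr2 (4.56), the elastase gene Mmp12 (4.43), the arginine transporter gene Slc7a2 (4.09) and the mannose receptor gene Mrc1 (1.47) also rose. The lectin gene Cd207 fell by 3.83, the thrombospondin gene Thbs1 by 3.67, the prostaglandin-degrading enzyme gene Hpgd and the integrin gene Itga9 by 3.59 each, Abcg3 by 3.38, Cxcr3 by 3.36, Igfbp4 by 3.08 and Cd55 by 3.01. Abca1 fell by 0.23 and Abcg1 rose by 0.29.

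Alternative activation genes rose in 26 of 30 tested members and fell in 2, Pparg (-0.22) and Il4ra (-0.15), as a list (adjusted p = 2.5e-14, adjusted p = 0.13 with an estimated correlation). Cholesterol biosynthesis genes rose in 23 of 24, including Idi1 (1.13) and Cyp51 (1.04) (adjusted p = 1.7e-08, adjusted p = 0.33 with an estimated correlation). All 13 MHC class II presentation genes rose, with Ciita, their transactivator, at 1.88 (adjusted p = 6.4e-06, adjusted p = 0.46 with an estimated correlation). Interferon-stimulated genes rose in 32 of 37, led by Gbp2 (3.35), and fell in 1, Ifitm3 by 0.43 (adjusted p = 5.3e-07, adjusted p = 0.50 with an estimated correlation). Of the classical inflammatory genes 18 of 31 rose, including Nos2 (4.60), Cd40 (3.47) and Ptgs2 (3.43), and 8 fell, including the interleukin genes Il10 (-2.18) and Il1b (-1.28) (adjusted p = 0.0138, adjusted p = 0.50 with an estimated correlation). Glycolysis and hypoxia genes were higher, 13 of 22 up and 4 down, with Pfkp at 2.09 and Vegfa at -1.19 (adjusted p = 0.0138, adjusted p = 0.50 with an estimated correlation). Adjusted over the list alone, these 6 lists gave the same counts of members up and down as over all genes.

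Macrophage identity genes were lower as a list, with 3 of 17 up and 10 down, among them Maf (-1.93) and Cd14 (-1.86) (adjusted p = 0.0138, adjusted p = 0.13 with an estimated correlation). Osteoclast markers were higher, 8 of 10 up and 2 down, with Ocstamp, Car2 (5.31) and Dcstamp (4.28), while Nfatc1 fell by 0.66 (adjusted p = 0.00275, adjusted p = 0.13 with an estimated correlation). Dendritic cell markers were higher in 5 of 7, led by the integrin gene Itgax (5.60), and lower in 1, Kit by 1.88 (adjusted p = 0.0259, adjusted p = 0.30 with an estimated correlation). Retinoid handling genes were higher in 8 of 14, with Aldh1a2, the plasma retinol carrier gene Rbp4 (3.95) and Dhrs9 (2.11), and lower in 3, with adjusted p = 0.0446, and adjusted p = 0.22 with an estimated correlation. Counts adjusted over the list alone were the same for these 4 lists. Retinoic acid-inducible genes went both ways under IL4: Rarb (2.54), Hic1 (2.14) and Dhrs3 (0.32) rose, and 6 of 10 fell, including Rxra (-1.16) and Tgm2 (-1.03) (list adjusted p = 0.31; 3 and 6 adjusted over the list alone). The values of Rarb and Hic1 are inexact because of their low levels in naive vehicle. Cyp26b1, at or below -2.08 log2 CPM in both groups, differed by 0.06 (adjusted p = 0.89) and by -1.10 after quantile normalization (adjusted p = 0.0113). The eosinophil lectin gene Siglecf rose by 5.43 and Ccr3 by 0.57, and the T cell receptor chain gene Cd247 rose by 0.88. The megakaryocyte markers Pf4 (-0.21) and Ppbp (-0.14) were not called. These lists had under 5 tested members, and no mitochondrially encoded gene was analysed here.

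IL4 changed 7285 of 12116 genes in vehicle, 3693 higher and 3592 lower (7100 without overlap, largely through the selection of called genes). Of these 7285 genes 1272 reached 1, 815 higher and 457 lower. Retinoid handling lost its call without naive RA library 2 (0.0506) or IL4 RA library 2 (0.0564), 3 (0.0554) or 4 (0.0525). Cell cycle genes (12 of 31 up, 1 down) and stromal and endothelial markers (5 of 10 down) missed the threshold at an adjusted p of 0.0802 each and passed it with the replicate block (0.0451 and 0.0148). Adjusted over the list alone they had 12 up and 1 down, and 4 down. The cell cycle list also passed without naive vehicle library 2 (0.0183) or IL4 vehicle library 3 (0.0303), and the stromal list without IL4 vehicle library 2 (0.0356).

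What IL4 does in cells then given RA was compared with this. Retnla rose by 10.94, Chil3 by 9.33, Ccl17 by 8.43, Arg1 by 8.33, Aldh1a2 by 8.24 and Mgl2 by 7.72, and Cd207 fell by 4.56, Thbs1 by 3.65 and Hpgd by 3.63. In naive RA, Retnla, Ccl17 and Aldh1a2 all lay at or below -2.25 log2 CPM, so their folds are again inexact. Rarb rose by 1.89 and Hic1 by 3.40, whereas Abca1 (0.11, adjusted p = 0.18) and Abcg1 (0.02, adjusted p = 0.84) were not called. Alternative activation genes rose in 28 of 30 and fell in 1 (adjusted p = 3.8e-16), cholesterol biosynthesis genes rose in 24 of 24 (1.1e-10), MHC class II genes in 13 of 13 (8.1e-06) and interferon-stimulated genes in 26 of 37, with 2 lower (0.0012). With an estimated correlation these were adjusted p = 0.11, 0.25, 0.46 and 0.57. Glycolysis and hypoxia genes had 15 of 22 up and 2 down (1.6e-04), osteoclast markers 8 of 10 up and 2 down (9.9e-04), macrophage identity genes 4 of 17 up and 11 down (0.0186) and dendritic cell markers 5 of 7 up and 2 down (0.0274). Classical inflammatory genes had 18 of 31 up and 9 down (0.0424), stromal and endothelial markers 0 of 10 up and 5 down (0.0424) and retinoid handling genes 8 of 14 up and 4 down (0.0493). All 7 were lost with an estimated correlation (lowest adjusted p = 0.11). Adjusted over the list alone, interferon-stimulated genes had 28 up and 2 down and classical inflammatory genes 18 up and 10 down. The other lists kept their counts.

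IL4 changed 6747 genes in RA, 3516 higher and 3231 lower (6540 without overlap, largely through the selection of called genes). Called in both arms with the same sign were 3100 genes up and 2813 down, where independence would give 1072 and 958, and 8 had opposite signs. These contrasts share no library, but they share the estimate of each gene's spread, which can raise the number called in both. The classical list lost its call without naive RA library 2 (0.0574) or IL4 RA library 2 (0.0739), and the stromal list without naive RA library 2 (0.0574) or IL4 RA library 3 (0.120). The stromal list also lost it after median centring (0.0625). Retinoid handling lost its call without naive vehicle library 3 (0.050003), naive RA library 2 (0.0574), IL4 vehicle library 2 (0.0579), 3 (0.0506) or 4 (0.0615) or IL4 RA library 2 (0.0526) or 3 (0.0741).

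The labels place RA in naive beside RA in IL4 macrophages, and both effects were compared directly. Genes called in both with the same sign numbered 516, with 313 up against 25.5 expected from independence and 203 down against 19.0, while 2 had opposite signs, Abcb1b (-0.33 and 0.30) and Inf2 (-0.25 and 0.33), which are named after their values were seen. Both effects use the same estimate of each gene's spread, which can raise the number called in both above independence without a shared effect. Of the 1657 genes called in either state 91.4% had the same sign, and the changes correlated across all genes at Pearson r = 0.60 and Spearman rho = 0.48. Without naive vehicle library 4 the number shared was 335.

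**Figure D2:**
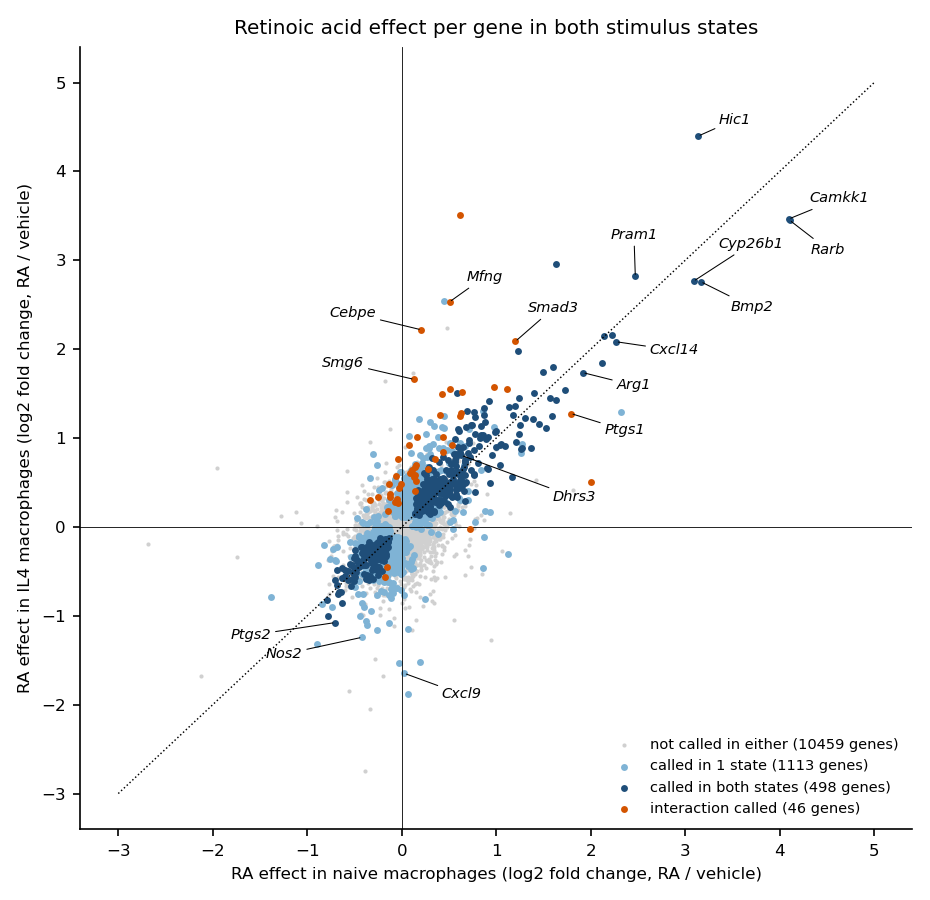
RA effect in naive cells (horizontal axis) against that in IL4 cells (vertical axis), as log2 fold change, for each of the 12116 genes; the dotted line marks equal effects. The 46 genes with a called interaction are orange, and 41 of them lie above the line.

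Tested as a difference, the RA response depended on IL4 for 46 genes, 41 with a larger and 5 with a smaller value in IL4 cells (1006 at an unadjusted p under 0.05). Mfng (Entrez 17305, chromosome 15, 78755882 to 78773516, minus strand) rose by 0.51 with RA in naive and 2.53 in IL4 cells, an interaction of 2.03 (SE 0.11, adjusted p = 1.9e-06). Smg6, a nonsense-mediated decay endonuclease gene that adjoins Hic1 on chromosome 11, differed by 0.13 in naive cells (adjusted p = 0.34) and rose by 1.66 in IL4 cells, an interaction of 1.53 (SE 0.10, adjusted p = 5.8e-06). The actin-binding protein gene Rai14 (1.06, adjusted p = 8.5e-05), Smad3 (0.88, adjusted p = 0.011) and the heparan sulfate enzyme gene Ndst1 (0.87, adjusted p = 8.6e-05) also had larger log2 changes with RA in IL4 cells. Smad3 nonetheless gained fewer CPM there (12.1) than in naive cells (22.4). The interleukin receptor gene Il21r rose by 0.72 in naive cells and differed by -0.03 in IL4 cells, an interaction of -0.75 (SE 0.09, adjusted p = 0.0034). These 6 genes kept their call without each of the 12 libraries. Arg1 (-0.18, adjusted p = 0.885), Rarb (-0.66, adjusted p = 0.62), Tgm2 (0.41, adjusted p = 0.10), Abca1 (0.34, adjusted p = 0.24), Abcg1 (-0.27, adjusted p = 0.54), Dhrs3 (0.17, adjusted p = 0.36), Cyp26b1 (-0.32, adjusted p = 0.90), Retnla (0.24, adjusted p = 0.92), Chil3 (0.23, adjusted p = 0.93) and Mrc1 (0.08, adjusted p = 0.88) were not called. The values of Arg1, Rarb, Cyp26b1 and Retnla rest on low levels in naive cells and are inexact. With library weights Tgm2 was called (0.35, adjusted p = 0.0465). All 41 genes with a larger value were called up by RA in IL4 cells. In naive cells 16 of them were also called up, 23 were not called, and 2 were called down, Abcb1b and Inf2.

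Camera called 7 lists for the interaction, and 0 with an estimated correlation or by fry. Interferon-stimulated genes had 37 of 37 negative values and a median of -0.39 (adjusted p = 1.5e-12, adjusted p = 0.47 with an estimated correlation), with 0 members called, also adjusted over the list alone. The count of 46 was 26 without naive vehicle library 2, 22 without naive vehicle library 4, 27, 17 and 22 without naive RA library 2, 3 and 4, 20 without IL4 vehicle library 3, and 22, 21 and 30 without IL4 RA library 2, 3 and 4.

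**Figure D3:**
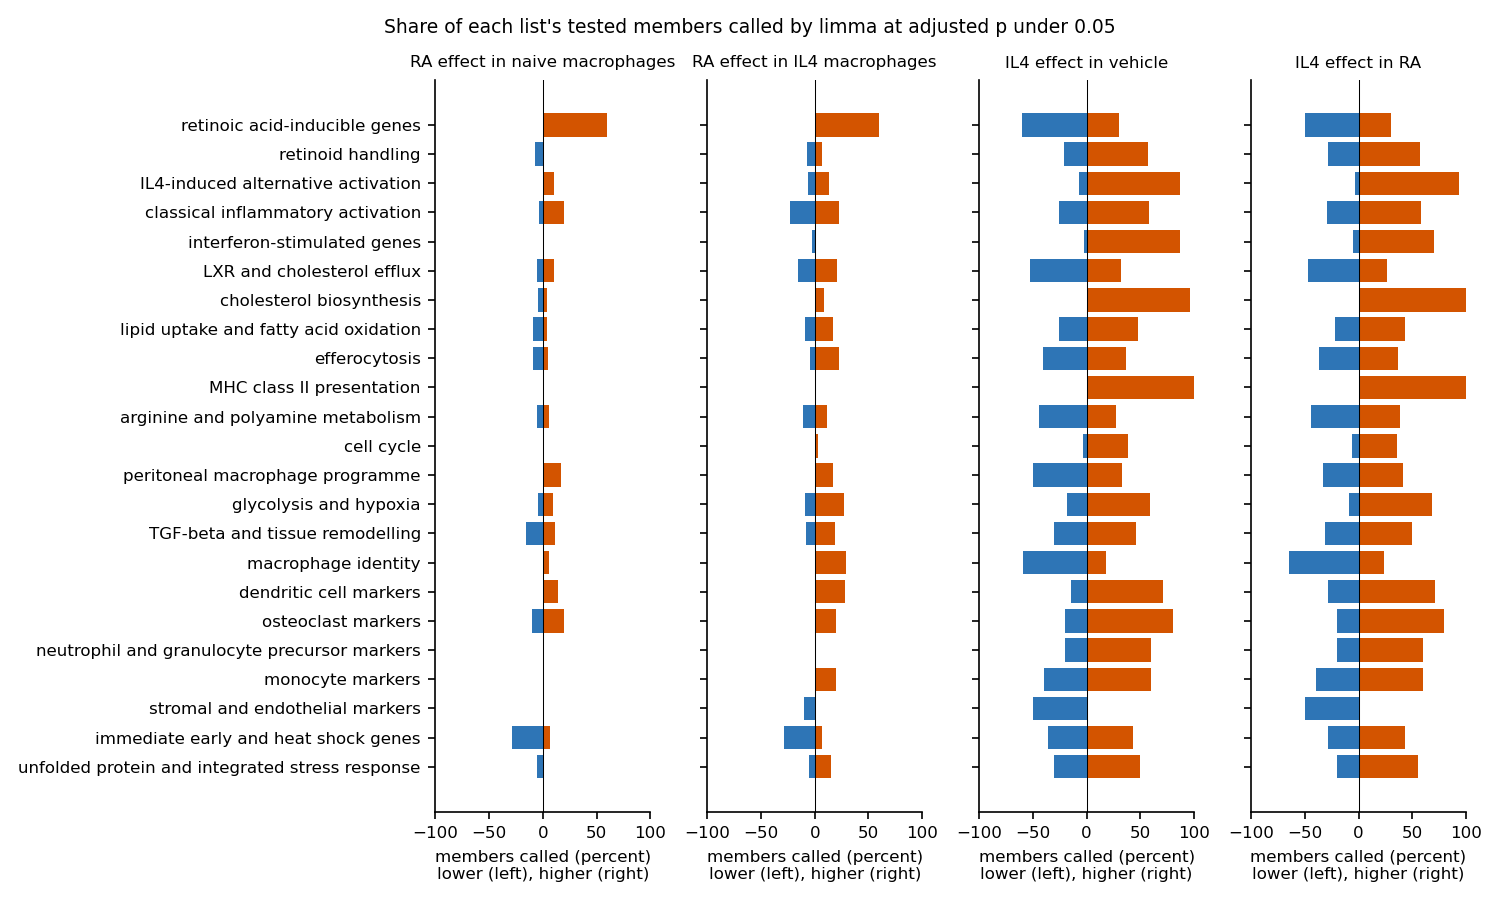
Percent of the tested members of each of the 23 lists that were called lower (blue, left) or higher (orange, right), in 4 contrasts. RA called 6 of 10 retinoic acid-inducible genes up in both states, and IL4 called all 13 MHC class II genes up.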

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

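The tests of a lower starting level, of differences between replicate numbers, of Smg6 with Hic1 and the others of the interferon-stimulated genes were chosen only after the result was seen. The label splits and the test of 1 aberrant library for the genes with a larger RA response were planned. Each result of this part stood out because the RA change in IL4 cells differed from that in naive cells by the interaction test (log2 difference, SE, Benjamini-Hochberg adjusted p from limma). Higher in IL4 cells were Mfng (2.03, 0.113, 1.9e-06), Cebpe (2.01, 0.362, 0.0325), Smg6 (1.53, 0.0990, 5.8e-06), Rai14 (1.06, 0.0886, 8.5e-05), Siglece (1.04, 0.164, 0.0182), Smad3 (0.88, 0.1301, 0.0109), Ndst1 (0.87, 0.0746, 8.6e-05) and Palld (0.85, 0.140, 0.0214). Lower were Cd200r1 (-0.29, 0.0485, 0.0251), Slc30a1 (-0.39, 0.0749, 0.0495), Ptgs1 (-0.52, 0.0821, 0.0190), Il21r (-0.75, 0.0930, 0.0034) and Pde1c (-1.49, 0.275, 0.0368). These 5 started higher in IL4 vehicle than in naive vehicle, such as Ptgs1 (5.95 against 4.83 log2 CPM) and Pde1c (2.67 against -1.57). The change in CPM was not compared for them. With RA, Cd200r1 (-0.16 in naive and -0.45 in IL4 cells) and Slc30a1 (-0.18, not called, and -0.56) had larger decreases in IL4 cells. Il21r rose in naive cells only (0.72 and -0.03). For Ptgs1 (1.79 and 1.28) and Pde1c (2.00 and 0.51, the latter not called) a lower log2 change need not be a smaller increase in CPM.

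Of these 13 genes, Mfng, Smg6, Rai14, Smad3, Ndst1 and Il21r kept their call without each of the 12 libraries. Palld lost it without naive vehicle library 2 (0.0516), naive RA library 4 (0.0601) or IL4 RA library 3 (0.0648) or 4 (0.0550). Siglece lost it without naive vehicle library 4 (0.0594), naive RA library 3 (0.0675) or IL4 vehicle library 3 (0.0525), and Ptgs1 without naive vehicle library 4 (0.0521), naive RA library 3 (0.0687), IL4 vehicle library 3 (0.0526) or IL4 RA library 2 (0.0536) or 3 (0.0519). Cd200r1 lost it without naive vehicle library 2 or 4, naive RA library 2 or 3, IL4 vehicle library 2 or 3, or IL4 RA library 2 or 3 (0.0536 to 0.0840). Cebpe lost it without every library except naive vehicle library 2 and IL4 vehicle library 4 (0.0592 to 0.109), Pde1c without every library except naive vehicle libraries 3 and 4 (0.0573 to 0.115), and Slc30a1 without every library except naive RA library 2 (0.0575 to 0.156).

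Lists that camera called for the interaction had median differences of 0.137 for glycolysis and hypoxia (adjusted p = 1.5e-04), 0.136 for cholesterol biosynthesis (3.8e-04), 0.118 for TGF-beta and tissue remodelling (0.0038), 0.0984 for retinoic acid-inducible genes (0.0483), 0.0601 for efferocytosis (0.0483), -0.102 for classical inflammatory activation (0.0231) and -0.394 for interferon-stimulated genes (1.5e-12). With an estimated correlation they were adjusted p = 0.467, 0.467, 0.365, 0.467, 0.365, 0.660 and 0.467. Adjusted over the list alone, 3 glycolysis genes were higher and 1 lower, and 3 retinoic acid-inducible and 2 TGF-beta genes were higher. The classical list lost its call without naive vehicle library 2 (0.106), naive RA library 4 (0.0890), IL4 vehicle library 2 (0.506) or IL4 RA library 4 (0.295). Efferocytosis lost it without naive vehicle library 2 (0.0637), naive RA library 2 (0.0904) or 3 (0.0644), IL4 vehicle library 2 (0.0734), 3 (0.0658) or 4 (0.0517), or IL4 RA library 2 (0.0570) or 4 (0.136). The retinoic acid-inducible list lost it without naive vehicle library 3 (0.236), naive RA library 2 (0.111) or 4 (0.0556), IL4 vehicle library 2 (0.0597), 3 (0.0557) or 4 (0.113), or IL4 RA library 2 (0.0968), 3 (0.0539) or 4 (0.0718).

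Swapping labels argued against chance for the number of called interaction genes, both directions together. Of 100 drawn swaps 1, the real one, gave 42 called genes in the fit used for swaps, which subtracts both main effects. The highest other gave 6. This covers the count and no single gene. The next tests were made on the 41 genes with a larger RA response in IL4 cells. A lower starting level in IL4 cells that turns the same increase in CPM into a larger fold does not apply to 9 genes, among them Rai14, Palld and Cebpe, that did not start lower in IL4 vehicle, and was argued against for 27 of the 32 that did, among them Mfng, Smg6 and Ndst1, whose CPM increase was larger in IL4 cells beyond its 95% interval. For the other 5 it cannot be told apart from a larger response: Smad3 (12.1 CPM in IL4 against 22.4 in naive cells), Siglece (23.8 against 32.7), Rab20 (52.6 against 60.3) and Neurl3 (147 against 175) gained less in IL4 cells, and the interval of Retreg1 reached 0 (the last 3 were named after their values were seen). Without any 1 library, 41 of 41 kept an interaction above 0 at an unadjusted p under 0.05 (highest 0.000741). Each kept at least 82.1% of its size. The 41 were chosen by small p-values in these same libraries, so this outcome was likely beforehand. It therefore cannot decide against a single aberrant library as the whole cause. The adjusted call was kept by 14 without each of the 12. It was kept by 20, 25 and 18 without naive vehicle library 2, 3 and 4. Without naive RA library 2, 3 and 4 it was kept by 23, 16 and 19. Without IL4 vehicle library 2, 3 and 4 it was kept by 26, 18 and 35. Without IL4 RA library 2, 3 and 4 it was kept by 21, 18 and 24. Differences between the replicate numbers that all groups share were argued against by the design, since each group holds each number once and they cancel. Fitting the number as a block leaves the differences between groups unchanged and is no separate test of this. It kept 46 of 46 calls, these 41 among them, and called 78 (67 up). No biological explanation was singled out.

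Smg6 and Hic1 lie next to each other on chromosome 11 on opposite strands, 116 bases apart in GENCODE, while their RefSeq models share 3072 bases. Transcripts or reads of the adjacent gene Hic1 counted as Smg6 could explain the rise of Smg6, in which case Smg6 would gain a fixed number of CPM per CPM of Hic1. In IL4 cells Smg6 gained 2.75 CPM per CPM of Hic1 (95% interval 2.08 to 3.42) and in naive cells 1.504 (-0.539 to 3.55). The intervals overlap, as the explanation needs, but the naive interval spans 0, so this and a response of Smg6 itself cannot be told apart. The annotation release and strand setting used to count the reads are not in the labels, which keeps it open.

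Interferon-stimulated genes were lower with RA in IL4 cells, with a mean difference of -0.388 (exact permutation p = 0.1, the smallest that 3 against 3 can give). Differences between replicate numbers that both arms share were argued against by the design, since each arm holds each number once and they cancel. The same-numbered differences were -0.478, -0.465 and -0.221. With the number fitted as a block the list stayed called with the preset correlation (adjusted p = 9.89e-07). The block leaves the differences between groups unchanged and is no separate test. The list stayed called with the preset correlation without any 1 of the 6 libraries (highest adjusted p = 0.00063). Its members varied almost together (estimated correlation 0.936), which the preset correlation does not allow for. That call therefore cannot decide against 1 aberrant library. The list mean, centred over the 12 libraries, was 0.843, 0.667 and 0.409 in IL4 vehicle and 0.364, 0.202 and 0.188 in IL4 RA. The direction of the difference therefore did not rest on 1 library. A spread of the whole list between libraries of 1 group as large as the difference stays a possible explanation. The SD of the list mean was 0.218 in IL4 vehicle and 0.098 in IL4 RA, both below the difference. It was 0.295 in naive vehicle and 0.426 in naive RA. Camera with the estimated correlation and without the block gave an adjusted p of 0.8. The lower values may therefore reflect the libraries rather than RA.

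For the other contrasts the 6 libraries of 2 groups allow 10 splits, too few for a share under 0.05. As many called genes came from 1 of 10 splits, the real one, in each: 759 against 143 in the highest other for RA in naive cells, 1416 against 1 for RA in IL4 cells, 7285 against 0 for IL4 in vehicle and 6747 against 0 for IL4 in RA.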

How the results depend on the processing

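All alternatives of this part were planned, and no test here was chosen after the result was seen. Of 221 called results for named genes, 189 kept direction and call in every alternative except the fold threshold, and 32 lost the call in at least 1. Cyp26b1 under IL4 in vehicle differed by 0.06 and by -1.10 after quantile normalization (adjusted p = 0.0113); the cause was not tested. Quantile normalization also lowered the share of increases among IL4 changes from 50.7% to 42.0% in vehicle and from 52.1% to 42.2% in RA. With median centring decreases outnumbered increases for RA in naive cells (372 up, 429 down), RA in IL4 cells (711 up, 752 down), IL4 in vehicle (3385 up, 3969 down) and IL4 in RA (3242 up, 3703 down). With library weights RA called 1950 genes in naive cells instead of 759, 875 genes were shared between both RA effects instead of 516, and the interaction called 103 instead of 46; it called 15 without the intensity trend. The cause was not tested. With changes of at least 1 (log2) the counts were 50, 95, 1272, 1168 and 7 in the order RA in naive cells, RA in IL4 cells, IL4 in vehicle, IL4 in RA and interaction, and 34 genes were shared, which the threshold itself brings about.

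With the replicate block the interaction called 78 genes, and 4 lists were called for RA in naive cells instead of 2, with classical inflammatory activation and cell cycle added (0.0209 each). It ended the calls of retinoid handling for IL4 in RA (0.0592) and of retinoic acid-inducible genes for the interaction (0.0674), and made cell cycle a call there (0.0048). The cause was not tested. Where the numbers pair the libraries, for RA in IL4 cells and IL4 in vehicle, the block changed no call of a list or named gene apart from cell cycle and stromal and endothelial markers. The reported counts come from the fit without the block. With it, 1664 genes were called for RA in IL4 cells instead of 1416, and 7556 for IL4 in vehicle instead of 7285. Lists called by camera with the preset correlation numbered 2, 5, 10, 11 and 7. With an estimated correlation they were 0, 0, 0, 0 and 0. Losses included lists whose estimated correlation lay below the preset 0.01. For RA in IL4 cells these were macrophage identity (0.0034) and the peritoneal macrophage programme (0.0092). A higher correlation between members therefore does not account for every loss. The cause was not tested. Fry gave 23 for IL4 in vehicle, 20 for IL4 in RA and 0 for the interaction. The cause was not tested.

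Leaving out 1 library gave 416 to 885 genes for RA in naive cells, 894 to 1498 for RA in IL4 cells, 6614 to 7468 for IL4 in vehicle, 6102 to 6797 for IL4 in RA, 17 to 67 for the interaction and 335 to 573 shared genes, with fewer samples in the fit. The lowest were without naive vehicle library 4 (416, 6614 and 335), IL4 RA library 3 (894) and naive RA library 3 (6102 and 17). Lists called ranged over 1 to 5, 3 to 6, 9 to 11, 8 to 11 and 4 to 7. A change of a pseudocount was not run, because the values are already on the log2 scale. Depth was estimated only. Among 7370 genes above 16 CPM, the median squared difference between replicates was 2.83 to 8.15 times that of counting, and what depth limits below that level was not computed.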

Other observations

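The hypothesis of this part was tested as planned, although the 3 increases and 6 decreases of the fixed list of retinoic acid-inducible genes under IL4 had been seen by then. Immediate early and heat shock genes went both ways: with RA, Dusp1 (-0.68 in naive and -0.75 in IL4 cells) and Fos (-0.50 and -0.56) fell and Ier3 rose (0.61 and 0.43), with 1 of 14 up and 4 down in each state (list adjusted p = 0.214 and 0.198). Under IL4 in vehicle Hspa1a rose by 2.55 and Fos fell by 1.24. Stress response genes under IL4 numbered 10 up and 6 down of 20 (adjusted p = 0.303), with the serine synthesis gene Psat1 at 2.38 and the cystine transporter gene Slc7a11 at 1.98, while RA lowered Slc7a11 (-0.60 in naive and -0.49 in IL4 cells). Pf4, a platelet chemokine gene, rose with RA by 0.90 in naive and 0.98 in IL4 cells, and Ppbp, the other tested megakaryocyte marker, by 1.27 in naive cells (adjusted p = 0.0203), while its 0.93 in IL4 cells was not called (adjusted p = 0.0591).

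Aldh1a2, which makes RA from retinaldehyde, rose by 8.23 with IL4 in vehicle, an inexact fold from naive values at or near the lowest. As a hypothesis, retinoic acid signalling may already be raised in IL4 cells given vehicle, as the rise of Aldh1a2 would allow. Genes that RA raises should then also be raised by IL4. Of the 788 genes called up by RA in IL4 cells, 30.1% were called up by IL4, against 30.5% of the other genes (Fisher exact p = 0.81), and 47.5% were called down, against 28.4%. The IL4 vehicle libraries shared by both contrasts bias this towards decreases. Of the 392 called up by RA in naive cells it was 40.3% against 30.2% (Fisher exact p = 2.7e-05), where the shared naive vehicle libraries bias it towards increases, and 37.2% against 29.4% were called down. Of the 313 called up by RA in both states it was 34.5% against 30.4% (Fisher exact p = 0.12), and 43.5% against 29.3% were called down. The covariance of the 2 effects in naive cells was 0.0126, above that of 100 simulations of the shared controls alone (mean 0.00892, highest 0.0111). The simulations drew each gene independently, while genes were correlated here (0.936 among interferon-stimulated genes). Their range is therefore too narrow to decide. The correlation was 0.0769 against a simulated mean of 0.501, but the simulations held no true effects, so the 2 are not alike. The share among genes chosen in IL4 cells, which the hypothesis needs to be raised, was not, but the shared libraries bias it downwards. The hypothesis and its absence therefore cannot be told apart here. Genes are not independent replicates, and RA itself was not measured.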
